A study of Mus musculus with 13 samples.

How the data were processed

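Small-intestinal tumours of ApcMin mice, which carry a germline Apc mutation and develop intestinal adenomas, were profiled by droplet-based single-cell RNA sequencing. The tumours came from untreated mice (control, 5 libraries) or from mice that had received 2 Gy of ionising radiation (IR) 1 day (3 libraries), 2 days (2 libraries) or 7 days (2 libraries) before, per the labels' titles. Of the 13 samples described, 12 were analysed; a wild-type sample was not analysed here. The design text also names tamoxifen-induced lineage tracing of PROX1-positive cells, and the labels do not say which libraries came from traced mice, so no library was assigned to that part. The labels of control replicates 1 and 2 carry another protocol text than the others and no library name, so these may be another batch, and fits without them were made as an alternative. The titles call the libraries biological replicates, whereas the protocol text of most of them speaks of data pooled from several mice and repeated experiments, so the p-values below measure the spread between these libraries.

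The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode. Alignment and counting with Cell Ranger 6.1.2 against the mm10 build were named in the submitters' processing notes. Per the file headers, counts from Cell Ranger 6.1.2 were deposited for control replicates 1 to 3 and IR 1 d replicates 1 and 2 (5 libraries), and counts from version 7.0.0 or 7.0.1 for control replicates 4 and 5, IR 1 d replicate 3 and all IR 2 d and IR 7 d libraries (7 libraries). No normalisation by the authors was recorded for these values. Gene names were taken from the deposited features list of the wild-type sample, whose genes are in the same order as the matrix lines, and 3 libraries hold 1 additional line, named for the tdTomato reporter in that list, which entered no comparison. These are control replicate 5 and both IR 2 d libraries. The line alone shows that the reference held the reporter. It held 775 UMIs in control replicate 5, and 2553 and 410 in IR 2 d replicates 1 and 2, so reporter RNA was counted in these libraries. In each, a larger share of epithelial cells with a Prox1 UMI than of those without had a reporter UMI. The other libraries have no such line, so reporter RNA could not be counted there. The labels give neither reporter genotype nor tamoxifen by library, so a difference in either between IR 2 d and control is not excluded. Gene positions are those of the GENCODE vM21 annotation of GRCm38 (mm10), in which 99.61% of the gene identifiers were found.

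Barcodes with at least 500 genes and at most 25% mitochondrial UMIs were kept as cells. This left 50609 of 119929 barcodes, between 2608 and 7649 per library. Scrublet, run per library with an expected doublet rate of 0.06, called 48 cells (0.095%), which is too few for the caller to have worked; doublets are therefore largely still present, and the removal of the 6% of barcodes with the highest scores was tried as an alternative. Cells were clustered with scanpy 1.11.5 on 2000 variable genes centred within each header version, 40 principal components, 20 nearest neighbours and the Leiden algorithm (leidenalg 0.10.2) at resolution 1, with Prox1 left out and seed 1. A cluster was named from markers fixed beforehand when at least 3 of them were higher and their mean log2 fold was at least 2 for broad classes or 1 for epithelial classes. The epithelial classes also needed a lead over the next class of at least 0.5. The broad name epithelial was given in another way, to clusters that met no other broad class. Such a cluster needed epithelial markers detected in at least 65% of cells on average, and UMIs per cell not far below those of its library. No minimum fold of the epithelial markers was asked for. These naming limits were set after the clusters had been seen. The 28920 epithelial cells were clustered again in the same way. Clusters that met no such condition stayed unnamed, and they held 12.0% of all kept cells in control, 25.0% at 1 d, 12.4% at 2 d and 27.8% at 7 d. Among the epithelial cells the unnamed share was 38.4% in control, 30.2% at 1 d, 38.7% at 2 d and 41.4% at 7 d.

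UMI counts were summed per library over all epithelial cells, since cells are not replicates. The sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3, with all 12 libraries in a common fit. Standard errors (SE) were derived from the log2 fold change and the F statistic. For cells with at least 1 Prox1 UMI (Prox1-positive) against cells with 0 (Prox1-negative), the sums of the 5 control libraries were compared with the library as a block, with Prox1 itself left out. This was repeated without the clusters named enteroendocrine or tuft, because those normal cell types also express Prox1. The interaction of Prox1 status with IR at 1 d was fitted over the sums of all 12 libraries. Shares of cells were compared with exact two-sided permutation tests of the mean share per library, also after each cell had been thinned to 3000 UMIs with shallower cells left out. A share was computed for libraries with at least 10 cells of the class, and intervals of single libraries are 95% Wilson intervals that cover counting error only.

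Gene lists were fixed beforehand: 16 lists of pathways and cell states, 10 of epithelial classes and 14 of other cell classes. The pathway lists cover p53 targets, S phase, G2/M, DNA repair, apoptosis, interferon response, MHC class I and II, Wnt targets, Notch, YAP targets, immediate early and dissociation genes, hypoxia and glycolysis, cholesterol synthesis, inflammation and antimicrobial genes, and mitochondrially encoded genes. Some lists overlap: 5 of the 26 measured p53 targets are also in the apoptosis list, all 9 adenoma Wnt-high markers are also Wnt targets, and 8 of 8 proliferating markers are also in the G2/M or S phase lists. Each list was tested with limma 3.58.1: camera asks whether a list moved relative to the other genes (preset inter-gene correlation 0.01, and estimated correlation beside it), and fry asks whether its genes moved, on balance, in a given direction without comparing them with other genes. Adjustment was over the lists within a comparison, and members past the threshold were counted over all genes and adjusted over the list alone; lists with fewer than 3 measured genes were not tested. The genes named in the text followed a rule: the 10 highest and 10 lowest log2 fold changes among called genes with a mean log2 CPM of at least 4 and with the libraries of the groups fully apart, leaving out unnamed gene models. It also took a panel of 31 genes and the 2 highest and 2 lowest adjusted p of a described list. Genes outside the rule are said to be so.

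Groups, tests, lists, the naming rule for genes and most alternatives were chosen before the data were examined. The alternatives chosen then were DESeq2 size factors (RLE) in edgeR, DESeq2 1.42.0, no expression filter, cells with at least 1000 genes and at most 15% mitochondrial UMIs, doublets kept, and an epithelial gate on single cells. They also included fits with only the groups compared, replicate numbers as a block, control replicates 3 to 5 only, each library left out in turn, 2 Prox1 UMIs, Prox1-negative cells matched for total UMIs, Leiden resolution 2 and estimated correlation. The header version as a covariate, fits within a header version and the removal of high doublet scores were added after the data had been seen. Each fit was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. Counts were drawn with the dispersions of that fit around a common mean per gene, and changed genes were taken above a minimum mean CPM. No shift between header versions was simulated, so recovery in the real libraries may differ. At 4-fold, edgeR recovered 52% at 1 d, 49% at 2 d, 62% at 7 d, 77% for all IR libraries, 37% for 7 d against 1 d, 99% for Prox1-positive against Prox1-negative cells with and without the enteroendocrine and tuft clusters, and 91% for the interaction. At 2-fold it recovered 7%, 4%, 3%, 22%, 0%, 78%, 87% and 54% of the changed genes in the same order, where the 78% and 87% belong to the fits with and without those clusters. At 1 d with the header version as a covariate, 57% of the 2-fold and 90% of the 4-fold changes were recovered.

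Before replicates were averaged they were compared: no pair of libraries agreed within sampling noise (chi-square per degree of freedom 85.4 or more). Total UMIs per library ranged from 59942819 to 199615170.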

Results

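Single cells of intestinal tumours from ApcMin mice were collected without irradiation and 1, 2 and 7 days after 2 Gy. Total UMIs were 119471253, 90982417, 90105298, 136828321 and 77495949 in control replicates 1 to 5. They were 59942819, 95069527 and 85173258 in IR 1 d replicates 1 to 3, 131538458 and 106698394 in IR 2 d replicates 1 and 2, and 199615170 and 69927735 in IR 7 d replicates 1 and 2. Of the 50609 cells kept, 28920 were epithelial. Epithelial cells made up 55.2% ± 12.1 (SD, n = 5) of control cells, 47.7% ± 20.97 (n = 3) at 1 d, 55.6% ± 16.4 (n = 2) at 2 d and 61.4% ± 9.62 (n = 2) at 7 d. In IR 1 d replicate 1, the library with most barcodes, 13.4% of barcodes were kept, and 23.4% of its cells were epithelial. The libraries fell into sets by the Cell Ranger version in their headers. The correlation of log CPM over genes (genes are not independent replicates) was 0.962 to 0.986 between libraries of the same version and 0.898 to 0.941 across versions. By edgeR, 7398 of 18368 genes differed between version 6 and version 7 control libraries. Values of the gene lists within a header version are therefore given beside the pooled ones where they could be computed.

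The comparison at 1 d asks how the epithelial cells of the tumour samples respond soon after irradiation. These cells were not limited to tumour cells. In control 18.3% of them were adenoma Wnt-high, 19.3% enterocyte and 6.21% goblet class. The results showed that genes activated by the p53 protein, the transcription factor that answers DNA damage, rose in the epithelial cells. Ephx1, which encodes a microsomal epoxide hydrolase (ENSMUSG00000038776, chromosome 1, 180976210 to 181020904 in GRCm38), rose after irradiation. It went from 6.29 ± 1.27 CPM (SD, n = 5) in control to 46.3 ± 15.2 CPM (n = 3), a log2 fold change of 2.88 ± 0.24 (SE; edgeR adjusted p = 0.0019). Its span overlaps another gene on the same strand. Ccng1 (cyclin G1, ENSMUSG00000020326, chromosome 11, 40748552 to 40755311) rose by 2.20 ± 0.27 and Zmat3 (a zinc finger RNA-binding protein, ENSMUSG00000027663, chromosome 3, 32334792 to 32366014) by 1.82 ± 0.24, with adjusted p of 0.018 and 0.024. Atg9b (an autophagy gene, ENSMUSG00000038295, chromosome 5, 24384181 to 24392143) rose from 8.82 ± 2.74 to 41.5 ± 21.3 CPM, by 2.23 ± 0.32 (adjusted p = 0.037). Gsdmc4, a member of the gasdermin C family of pore-forming proteins (ENSMUSG00000055748, chromosome 15, 63891264 to 63912297), fell, with a log2 fold change of -4.36 ± 0.51 (adjusted p = 0.018). Its neighbours, named after their values were seen, Gsdmc2 (-3.86 ± 0.43) and Gsdmc3 (-4.12 ± 0.47, adjusted p = 0.017 for both), fell too. Since these near-identical copies can share reads, their separate values are uncertain.

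In all, 16 of 19381 genes passed the edgeR threshold at 1 d, 12 higher and 4 lower, and 923 genes had an unadjusted p under 0.05. The other called genes, named after their values were seen, were Inka2 (4.30 ± 0.33), Psrc1, Mbl2, Sesn2, Hmcn2, Ddit4l, 1700007K13Rik and 9230114K14Rik among the higher genes. Pla2g4c (-3.56 ± 0.47) was among the lower. All 16 genes kept their direction in 25 of 25 alternatives, and Inka2 and Ephx1 stayed past the threshold in 12 of 12 fits that left out a library. The edgeR count was 0 with control replicates 3 to 5 only (664 at an unadjusted p under 0.05), 0 with the replicate number as a block (1043), and 2 with only the groups compared in the fit. With control replicates 3 to 5 only, Ephx1 stood at 2.90 and Inka2 at 4.31, each with an adjusted p of 0.070. The count was 51 with the header version as a covariate, with all 16 genes among them. It was 149 by DESeq2 and 4 within version 6. Within version 7 it was 3, where IR 1 d replicate 3 is the only irradiated library against 2 controls and is assumed to vary like the other groups. The values within version 7 at 1 d below rest on that library too. It fell to 4, 6, 5 and 2 genes without control replicates 1, 2, 4 and 5, and to 4 and 3 without IR 1 d replicates 1 and 2. It fell to 10 without either IR 2 d library and to 7 without either IR 7 d library.

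**Figure D1:**
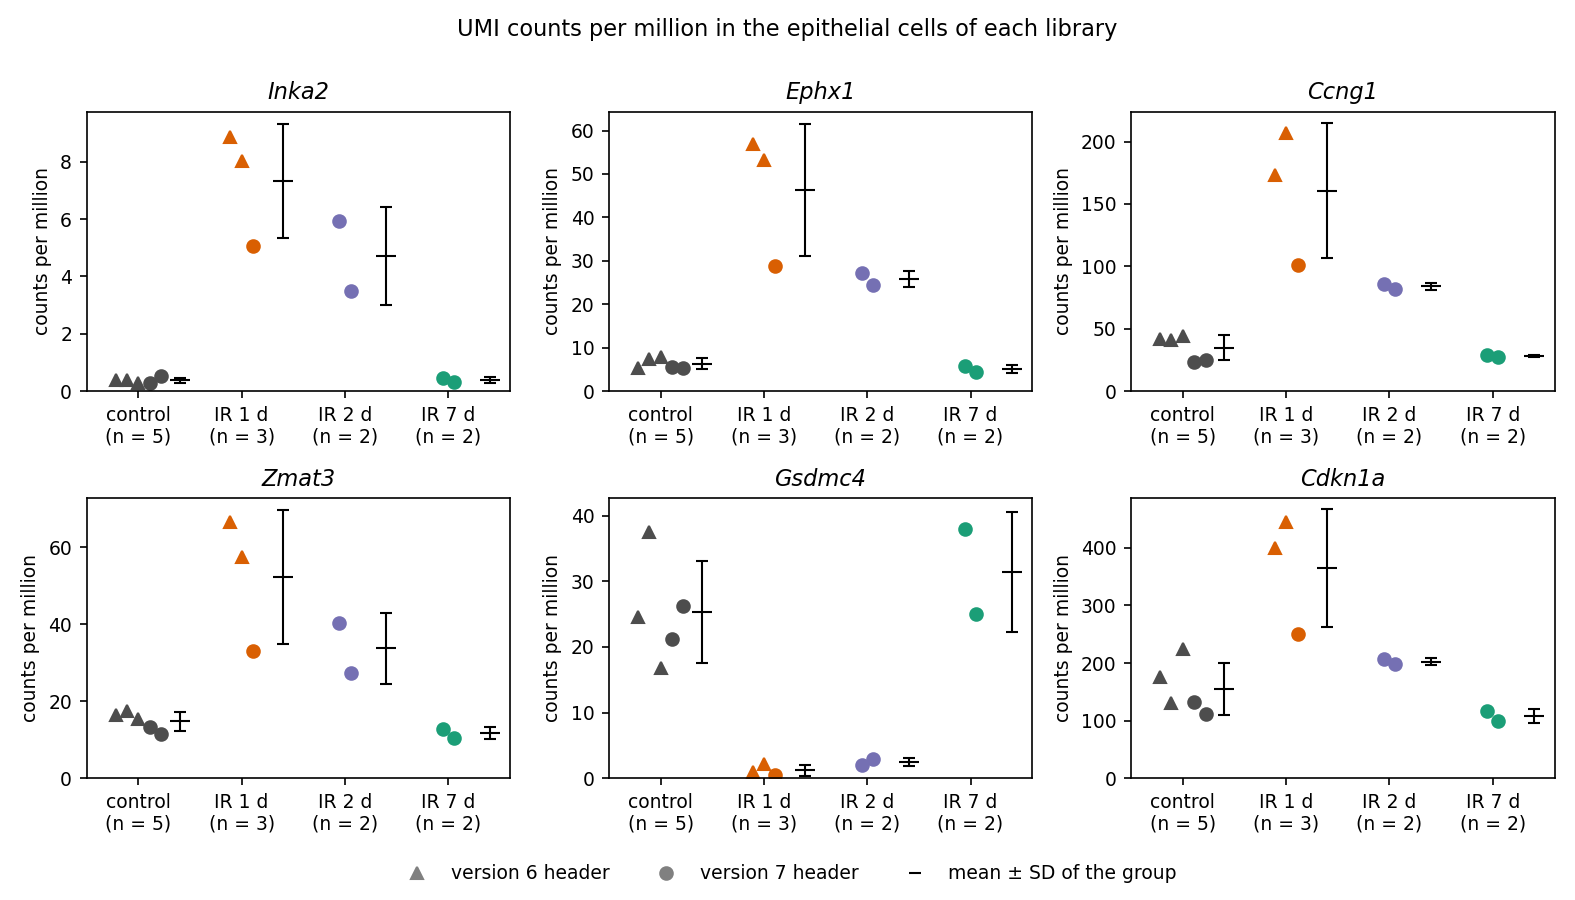
CPM of Inka2, Ephx1, Ccng1, Zmat3, Gsdmc4 and Cdkn1a in the epithelial cells of each library, by group; triangles are libraries with a version 6 header, circles those with a version 7 header, and bars show mean ± SD. Ephx1 averaged 6.29 CPM in control, 46.3 at 1 d, 25.9 at 2 d and 5.14 at 7 d.

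All 26 measured p53 targets had positive values at 1 d, with a median log2 fold change of 1.00; 3 members passed over all genes and 20 adjusted over the list alone. The list rose relative to other genes by camera (adjusted p = 3.2e-37, and adjusted p = 0.0020 with an estimated correlation). By fry its genes moved up on balance (adjusted p = 0.00013). The median was 1.10 within version 6 libraries, 0.83 within version 7 libraries and 0.98 with the version as a covariate. Among the panel genes of this pathway, Cdkn1a, the p21 inhibitor of the cell cycle (1.24 ± 0.25, adjusted p = 0.24), Bax (1.42 ± 0.23, 0.099), Eda2r (3.41 ± 0.53, 0.059), Bbc3 (1.32 ± 0.23), Trp53inp1 (1.62 ± 0.27), Phlda3 (1.59 ± 0.46) and Mdm2 (0.72 ± 0.16) did not pass over all genes. Pmaip1 (0.37 ± 0.51) and Perp (0.07 ± 0.20) had the highest adjusted p of the list. With the version as a covariate, Cdkn1a (adjusted p = 0.013), Bax (0.0021) and Eda2r (0.011) passed. The count over all genes fell from 3 to 0 without any of control replicates 1, 2, 4 and 5, IR 1 d replicates 1 and 2 or either IR 7 d library. It was 2 without control replicate 3 or either IR 2 d library, and 7 without IR 1 d replicate 3. The count over the list alone stayed between 16 and 20.

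Cell-cycle genes had lower values at 1 d, and fewer epithelial cells were of the proliferating class, which is named from such genes. Its share was 11.72% ± 4.45 (SD, n = 5) in control and 2.80% ± 1.11 (n = 3) at 1 d, with all 3 libraries below every control library. The G2/M list, genes of mitosis, had 0 of 18 members with a positive value and a median of -1.16; 0 members passed over all genes and 17 were lower when adjusted over the list alone. Camera called it (adjusted p = 5.1e-27), but not with an estimated correlation (adjusted p = 0.19). Cenpe, a kinetochore motor (-1.18 ± 0.25), and Kif11, a spindle motor (-1.26 ± 0.29), had the lowest adjusted p of the list, 0.30 and 0.38. Birc5 (-1.13 ± 0.46) and Ube2c (-0.75 ± 0.41) had the highest. S phase genes had a median of -0.82 with 0 of 20 positive. Of them, 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 1.8e-14, and adjusted p = 0.31 with an estimated correlation). Cdc45 (-0.96 ± 0.29) and Cdc6 (-1.02 ± 0.34) had the lowest adjusted p of that list, and Pcna (-0.42 ± 0.31) and Mcm7 (-0.55 ± 0.43) the highest. DNA repair genes of homologous recombination had a median of -0.81 with 0 of 13 positive. In this list 0 genes passed over all genes and 9 were lower adjusted over the list alone (camera adjusted p = 9.0e-15, and adjusted p = 0.18 with an estimated correlation). Values went from Fancd2 (-0.98 ± 0.25) and Blm (-0.78 ± 0.22) to Xrcc2 (-0.61 ± 0.33) and Brca1 (-0.23 ± 0.15). Within version 6 and version 7 libraries the medians were -1.14 and -1.20 for G2/M, -0.84 and -0.77 for S phase, and -0.89 and -0.71 for DNA repair. Adjusted over the list alone, 0 G2/M genes were left without IR 1 d replicate 1 or 3, while S phase gave 19 without control replicate 4 and 18 without IR 1 d replicate 2. DNA repair gave 0 without control replicates 1, 2 or 5 or IR 1 d replicate 1. It gave 2 without either IR 2 d library, 4 without IR 1 d replicate 3, and 6 without control replicate 3 or either IR 7 d library.

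Differentiation markers were called in the same comparison by camera with the preset correlation only. The medians were 0.57 for enterocyte markers (adjusted p = 0.0010, and adjusted p = 0.49 with an estimated correlation), 0.80 for goblet markers (1.2e-06 and 0.23) and 1.20 for Paneth markers (5.7e-04 and 0.27). They were -0.33 for stem markers (0.016 and 0.20) and -1.03 for proliferating markers (4.1e-09 and 0.23). In the same order they were 0.34, 0.36, 0.82, -0.08 and -1.03 within version 6 and 1.01, 1.58, 2.09, -1.07 and -1.10 within version 7. The apoptosis list had a median of 0.15 (adjusted p = 0.0093, and adjusted p = 0.18 with an estimated correlation), with 3 members higher adjusted over the list alone. The same held for MHC class II (-0.47, and adjusted p = 0.54 with an estimated correlation), whose direction turned between version 6 (-1.44) and version 7 (0.47). It also held for mitochondrially encoded genes (0.25, 0.54), cholesterol synthesis (-0.22, 0.54), inflammation and antimicrobial genes (-0.34, 0.23), B cell markers (-1.11, 0.49) and mast cell markers (-0.56, 0.54). Within version 6 and version 7 the medians were 0.10 and 0.40 for apoptosis, 0.10 and 0.53 for mitochondrially encoded genes, -0.18 and -0.32 for cholesterol synthesis, -0.26 and -0.32 for inflammation, and -0.21 and -0.65 for mast cells. The B cell median was -1.50 within version 7, where control replicate 5 is 1 of the 2 controls. B cells made up 26.8% of all cells in that library, against 0.06% to 0.89% in the other controls. Lists that camera did not call follow with the pooled median, then those within version 6 and within version 7. They were the interferon response (0.11, 0.17, -0.08), MHC class I (0.26, 0.11, 0.67), Wnt targets (0.03, 0.45, -0.57), Notch (0.04, -0.07, -0.06), YAP targets (0.17, 0.26, -0.39), immediate early and dissociation genes (0.05, 0.27, -0.10), and hypoxia and glycolysis (0.11, 0.03, 0.28). Among epithelial classes they were the markers of adenoma Wnt-high (0.11, 0.78, -0.87), enteroendocrine (1.20, 0.11, 2.57), tuft (0.30, 0.19, 0.62), regenerative or fetal (0.20, 0.34, -0.29) and M cells (0.24, -0.04, 0.33). The other classes were T cells (0.06, 0.07, 0.10), plasma cells (-0.29, -0.69, 0.13), macrophages (0.30, 0.29, -0.07), dendritic cells (-0.81, -0.53, -1.22), neutrophils (-0.65, -0.68, -0.86), fibroblasts (0.71, 1.08, -1.47), blood endothelium (-0.10, -0.01, -0.65), lymphatic endothelium (0.12, 0.27, -0.64), mural cells (0.07, 0.62, -0.23) and erythroid cells (0.63, 0.66, -2.40). NK or ILC markers had 0.33, and -0.47 within version 7. The adenoma Wnt-high markers were positive in 9 of 9 genes within version 6 and in 0 of 9 within version 7, so the pooled median hides opposite directions. Too few glia markers were measured. No panel gene of stem, Wnt or regenerative cells passed the threshold. Their values were Lgr5 (-0.86 ± 0.69), Olfm4 (-1.79 ± 0.71), Ascl2 (0.03 ± 0.36), Axin2 (0.11 ± 0.33), Notum (0.36 ± 0.52), Clu (0.51 ± 0.54), Ly6a (-0.11 ± 0.54), Anxa1 (-0.24 ± 0.41) and Prox1 (0.10 ± 0.45).

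At 2 d the p53 targets were still higher. Their median was 0.73 with 24 of 26 positive; 0 passed over all genes and 14 adjusted over the list alone. Camera called the list (adjusted p = 8.0e-11; adjusted p = 0.11 with an estimated correlation, and 0.0056 with the version as a covariate too). Fry gave an adjusted p of 0.0078, and the median was 0.73 within version 7, the version of both irradiated libraries. The count adjusted over the list alone was 3 without IR 2 d replicate 1 and 8 without IR 2 d replicate 2. Inka2 (ENSMUSG00000048458, chromosome 3, 105704599 to 105720842), named after its value was seen, was the single gene of 19381 past the edgeR threshold (3.66 ± 0.34, adjusted p = 0.0097). At an unadjusted p under 0.05 there were 524 genes (242 to 1575 in fits that left out a library), and DESeq2 called 37. The edgeR count at 2 d was 0 with control replicates 3 to 5 only (234 at an unadjusted p under 0.05). Inka2 was no longer past the threshold without control replicates 1, 2 or 3 or IR 2 d replicate 1 (adjusted p = 0.068, 0.068, 0.057 and 0.26). The count was 2 without IR 1 d replicate 3. With only version 7 libraries it was 0 by edgeR, with 700 at an unadjusted p under 0.05. Ephx1 (2.04 ± 0.26, adjusted p = 0.10) and Ccng1 (1.27 ± 0.30, 0.83) did not pass. With the version as a covariate they did (2.38 ± 0.21 and 1.82 ± 0.11). The cell-cycle lists were not called at 2 d, with medians of -0.13 for S phase, 0.04 for G2/M and 0.16 for DNA repair, and 0.48, 0.42 and 0.35 within version 7. Cholesterol synthesis (-0.32) and erythroid markers (-3.95) were called with the preset correlation (adjusted p = 0.023 and 0.040) and had an adjusted p of 0.94 with an estimated correlation, and their medians were -0.11 and -1.54 within version 7. No other list was called. Both IR 2 d libraries, and of the controls replicate 5 alone, hold the additional tdTomato line, with reporter UMIs in each. The other libraries have no such line, and a difference between the groups in reporter genotype or tamoxifen is not excluded by the labels.

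By 7 d the p53 targets were back near control, with a median of -0.04, 12 of 26 positive and a camera adjusted p of 0.69, and a median of 0.05 within version 7. Ephx1 stood at 5.14 ± 0.99 CPM (SD, n = 2). By edgeR 0 of 19381 genes passed against control, with 469 at an unadjusted p under 0.05 (217 to 1239 in fits that left out a library) and 16 called by DESeq2. Interferon response genes, which answer viral and inflammatory signals, were lower by camera with the preset correlation (median -0.88, 2 of 18 positive, adjusted p = 2.3e-09; adjusted p = 0.38 with an estimated correlation; -0.69 within version 7). Oasl2 stood at -1.47 ± 0.47 and Ifi44 at -1.53 ± 0.50, and at the other end of the list Bst2 at -0.21 and Oas1a at 0.02. Goblet markers had a median of -1.24 (adjusted p = 1.4e-06; adjusted p = 0.38 with an estimated correlation; -0.72 within version 7). In this list 0 members passed over all genes and 5 were lower adjusted over the list alone, among them the mucus genes Fcgbp (-1.38 ± 0.34) and Clca1 (-2.28 ± 0.57). Lists called as lower with the preset correlation alone were also enterocyte markers (-0.87, and adjusted p = 0.61 with an estimated correlation), MHC class II (-1.21, 0.87), MHC class I (-0.56, 0.76), hypoxia and glycolysis (-0.36, 0.38), T cell markers (-1.39, 0.38) and mast cell markers (-0.63, 0.76). Lists called as higher in this way were inflammation and antimicrobial genes (0.63, 0.38), immediate early and dissociation genes (0.49, 0.87) and Paneth markers (1.44, 0.76). Within version 7 the medians of the MHC class I, hypoxia and immediate early lists were -0.15, -0.18 and 0.17. They were -0.51 for enterocyte, -0.99 for T cell, -0.65 for mast cell and 1.58 for Paneth markers, -1.50 for MHC class II and 0.70 for inflammation.

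**Figure D2:**
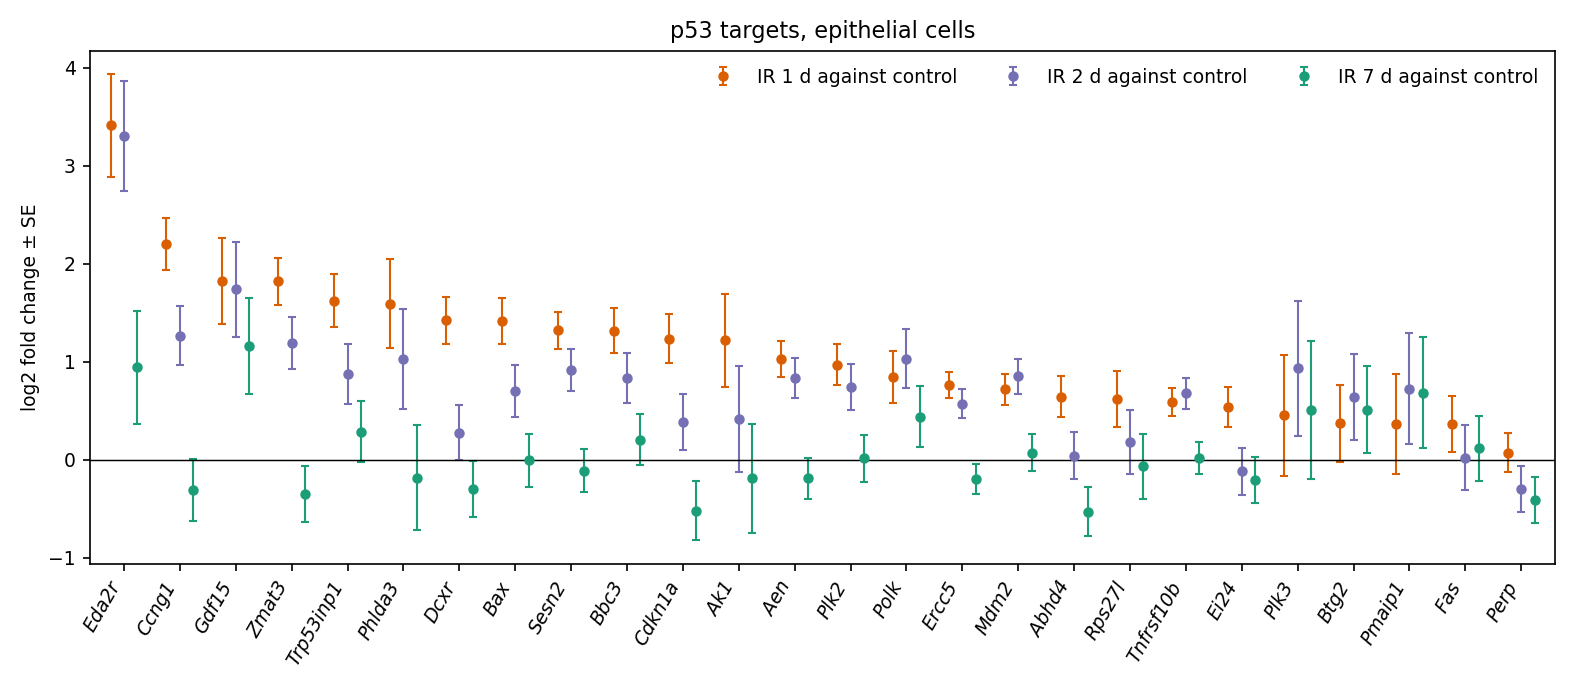
Log2 fold change (± SE) of the 26 measured p53 targets against control in epithelial cells at 1, 2 and 7 days after 2 Gy. The list medians were 1.00, 0.73 and -0.04.

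The difference between 7 d and 1 d was tested directly. Gsdmc2 (3.91 ± 0.46), Gsdmc3 (4.28 ± 0.50) and Gsdmc4 (4.67 ± 0.56) were higher at 7 d, and Ephx1 (-3.17 ± 0.35) and Inka2 (-4.22 ± 0.47) were lower, each with an edgeR adjusted p of 0.021. These were the 5 of 19381 genes past the threshold, of which Gsdmc2, Gsdmc3 and Inka2 were named after their values were seen. At an unadjusted p under 0.05 there were 1995 genes, and DESeq2 called 414. With all 5 among them, 10 were called with the version as a covariate. By edgeR the count was 0 without control replicate 1 or any of the IR 2 d and IR 7 d libraries, and 2 without control replicates 4 or 5. Without IR 1 d replicate 1 it was 1, a gene outside the 5, and without IR 1 d replicate 2 it was 1, Gsdmc4. It was 0 with control replicates 3 to 5 only (1821 at an unadjusted p under 0.05) and with only the groups compared in the fit (1396). The p53 targets fell (median -1.03, 17 lower adjusted over the list alone, camera adjusted p = 3.6e-15, adjusted p = 0.041 with an estimated correlation; 9 lower without IR 7 d replicate 2). G2/M genes had a median of 1.31, with 18 higher adjusted over the list alone (camera adjusted p = 9.3e-13; adjusted p = 0.35 with an estimated correlation), including Cenpe (1.43 ± 0.30) and Kif11 (1.53 ± 0.34). Of them, 2 were left without IR 1 d replicate 1 or 3 and 0 without IR 7 d replicate 2. Goblet markers had a median of -2.04, with 6 lower adjusted over the list alone and adjusted p = 0.30 with an estimated correlation. Within version 7, where IR 1 d replicate 3 alone stands for 1 d and is assumed to vary like the other groups, edgeR called 0 genes, with 2974 at an unadjusted p under 0.05. The values there were -2.53 for Ephx1, -3.71 for Inka2 and 5.996 for Gsdmc4 (adjusted p = 0.078, 0.20 and 0.078). The list medians were -0.75 for p53 targets, 1.78 for G2/M and -2.40 for goblet markers.

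All 7 irradiated libraries were set against the 5 controls as the mean of the times, each time with equal weight. The share tests below instead average the 7 libraries. Inka2 alone passed (2.68 ± 0.28, edgeR adjusted p = 0.033), with 344 genes at an unadjusted p under 0.05 (202 to 1194 in fits that left out a library) and 28 called by DESeq2. With control replicates 3 to 5 only, edgeR called 0 (145 at an unadjusted p under 0.05). Inka2 remained past the threshold in 1 of the fits that left out a library, the one without IR 1 d replicate 3, where 3 genes were called. The count was 1 without IR 1 d replicate 2, with another gene, and 0 in the other 10. With the version as a covariate 6 genes were called (Ccng1, Ephx1, Inka2, Bax, Mgmt and Zmat3). Within version 7 edgeR called 0, with 647 at an unadjusted p under 0.05. The p53 targets had a median of 0.57, with 25 of 26 positive, 0 past the threshold over all genes and 14 adjusted over the list alone (camera adjusted p = 2.5e-18, and adjusted p = 0.022 with an estimated correlation; 0.57 within version 7). Lists called with the preset correlation alone were S phase (-0.35), G2/M (-0.29), proliferating markers (-0.31), the interferon response (-0.21), MHC class II (-0.67), immediate early genes (0.36), hypoxia (-0.20), cholesterol synthesis (-0.19) and Paneth markers (1.24). Each had an adjusted p of 0.73 with an estimated correlation, and with the version as a covariate the medians of S phase (0.059), G2/M (0.0013) and proliferating markers (0.069) turned in sign. Within version 7 the medians of the 9 lists, in the same order, were 0.12, -0.06, 0.07, -0.14, -0.57, 0.11, 0.08, -0.08 and 1.53.

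The series title concerns a PROX1-positive tumour cell population. Prox1, a homeobox transcription factor (ENSMUSG00000010175, chromosome 1, 190118035 to 190170714), had at least 1 UMI in 39.3% ± 12.4 (SD, n = 5) of control epithelial cells. By class, in control, the share was 91.9% ± 3.07 in adenoma Wnt-high cells, at a median of 19080 UMIs per cell, and 76.6% ± 15.2 in proliferating cells (37395 UMIs). It was 67.9% ± 26.6 in tuft cells (11401 UMIs), 55.7% ± 8.6 in enteroendocrine cells (n = 4), 30.9% in goblet cells (25337 UMIs) and 8.29% ± 5.94 in enterocytes (21534 UMIs). T cells, which should lack Prox1, gave a background of 6.06% ± 3.8 at 3834 UMIs, and plasma cells 6.20% at 20073 UMIs. Thinned to 3000 UMIs per cell, the shares were 73.6% ± 8.7 in adenoma Wnt-high cells, 42.7% in proliferating cells, 46.48% ± 23.9 in tuft cells (n = 4), 24.92% ± 8.07 in enteroendocrine cells (n = 4), 7.19% ± 3.25 in goblet cells and 2.25% in enterocytes. As background they were 4.57% ± 3.10 in T cells and 2.08% ± 1.71 in plasma cells. Enterocytes lay near this background, whereas the goblet mean lay above both values. Of the Prox1-positive epithelial cells, 42.2% ± 8.67 (n = 5) were adenoma Wnt-high and 23.4% ± 7.22 proliferating, whereas 28.4% ± 11.6 of the Prox1-negative ones were enterocytes and 2.43% ± 1.44 adenoma Wnt-high.

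No difference in the share of epithelial cells with a Prox1 UMI passed the test after irradiation. It was 37.2% ± 18.9 (SD, n = 3) at 1 d, 29.1% ± 0.94 (n = 2) at 2 d and 43.0% ± 17.4 (n = 2) at 7 d, against 39.3% ± 12.4 in control. The exact two-sided permutation p was 0.89, 0.33 and 0.76, and 0.73 for all 7 irradiated libraries, and the smallest p these 4 comparisons allow is 0.018, 0.048, 0.048 and 0.0013. Single libraries ranged from 20.1% (95% Wilson interval 18.3 to 22.0) in control replicate 3 to 58.8% (54.8 to 62.6) in IR 1 d replicate 1, and median UMIs per epithelial cell from 10637 to 31719. After thinning the shares were 24.99% ± 9.00 in control, 24.6% ± 14.3 at 1 d, 16.9% ± 0.09 at 2 d and 24.7% ± 9.62 at 7 d, with 804, 427, 329 and 467 shallower cells left out. Within a header version the differences from control were 4.12 percentage points (version 6) and -13.6 (version 7) at 1 d, -13.6 at 2 d and 0.26 at 7 d. IR 1 d replicate 3 (29.1%), both IR 2 d libraries (29.79% and 28.46%) and IR 7 d replicate 2 (30.68%) lay below both version 7 controls (50.12% and 35.31%), and IR 7 d replicate 1 (55.27%) above them. The exact permutation p was 0.80, 0.67, 0.33 and 1.0 where the smallest possible p is 0.1, 0.33, 0.33 and 0.33, so these tests could not have passed and leave the differences open. For all irradiated libraries within version 7 the difference was -8.05 points, with a p of 0.48 in a test whose smallest possible p is 0.048. The pooled differences were -2.17 points at 1 d, -10.2 at 2 d and 3.64 at 7 d, and -2.81 for all irradiated libraries. At 1 d the difference turned positive without control replicates 2 (0.50) or 4 (0.53) or IR 1 d replicates 2 (4.596) or 3 (1.86), and was -13.0 without IR 1 d replicate 1. At 7 d it was -0.33 after thinning, -1.16 without control replicate 3 and -8.65 without IR 7 d replicate 1.

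**Figure D3:**
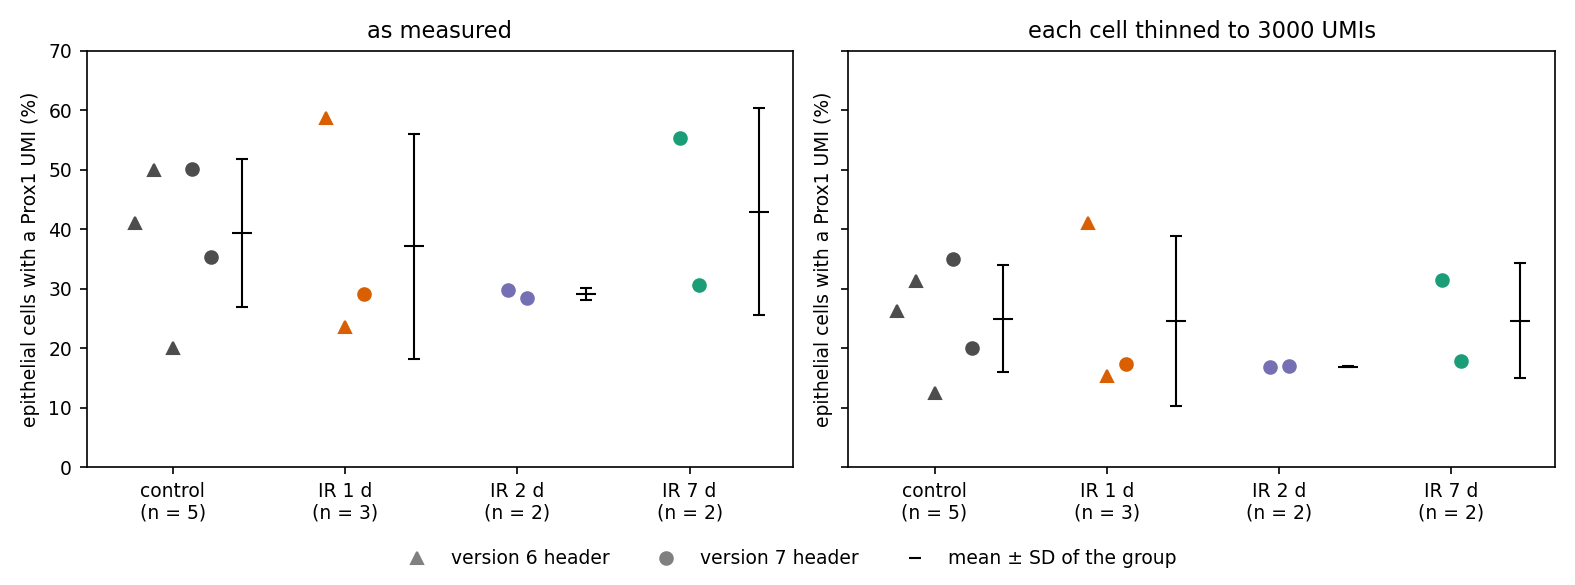
Percent of epithelial cells with at least 1 Prox1 UMI in each library, by group, as measured and after thinning each cell to 3000 UMIs, with mean ± SD. The control libraries spread from 20.1% to 50.1%, and the irradiated ones from 23.6% to 58.8%.

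Prox1-positive cells of control tumours differed from Prox1-negative ones over much of the transcriptome. Wnt targets were higher: Notum, a secreted Wnt deacylase (4.50 ± 0.22), Lgr5, a stem cell receptor (2.75 ± 0.22), Ascl2 (2.21 ± 0.19), Axin2 (1.94 ± 0.14) and Sox9 (1.41 ± 0.20) passed the test. Of the list, 17 of 17 members passed over all genes and adjusted over the list alone (median 2.21, camera adjusted p = 3.1e-06; adjusted p = 0.77 with an estimated correlation; fry adjusted p = 6.7e-04). Lef1 (4.88 ± 0.21) and Wif1 (5.61 ± 0.25) had the lowest adjusted p of the list, and Cd44 (0.93 ± 0.17) and Ephb2 (0.30 ± 0.11) the highest. The genes with the highest values under the naming rule were Mdga2 (6.60 ± 0.18), Spock2 (5.86 ± 0.23), Ptn (5.79 ± 0.37), Pnliprp1, Wif1, Serpina3n, Bpifb5, Ppp2r2b, Dkk3 and Sbspon (5.24 ± 0.20), with edgeR adjusted p from 4.6e-06 to 1.4e-05. Those with the lowest included the intestinal apolipoproteins Apoa4 (-3.97 ± 0.30), Apoa1 (-3.77 ± 0.28), Apoc3 (-3.73 ± 0.24) and Apoc2 (-3.67 ± 0.29), together with Clca4a, Clca4b, Ly6m, Ada, Bst1 and Leap2. In total 11245 of 18121 genes passed, 6079 higher and 5166 lower. Without the enteroendocrine and tuft clusters 11273 of 17961 did, 6104 higher and 5169 lower, where the Wnt median was 2.23. The makeup of the cell groups by class differed as given above, and median UMIs per cell over the libraries were 15227 to 40452 in Prox1-positive and 14160.5 to 29212 in Prox1-negative cells. Without the enteroendocrine and tuft clusters the tuft gene Dclk1 was 2.67 ± 0.14 and Pou2f3 1.32 ± 0.54 (adjusted p = 0.063).

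Proliferation genes were also higher in Prox1-positive cells. Each list described here as called by camera had an adjusted p of 0.77 with an estimated correlation. All 18 G2/M genes (median 0.81, camera adjusted p = 6.7e-04) and all 13 DNA repair genes (0.80, 0.0054) were higher, over all genes and adjusted over the list alone, as 17 of 20 S phase genes were over all genes and 18 adjusted over the list alone (0.87, 0.0054). Examples were Cenpf (0.97 ± 0.13), Plk1 (1.14 ± 0.17), Brca1 (1.06 ± 0.18) and Mcm4 (0.92 ± 0.16). Markers of adenoma Wnt-high cells had a median of 3.57 with 9 of 9 higher (7.1e-05). Enterocyte markers (median -3.54, 8 of 8 lower over all genes and adjusted over the list alone, camera adjusted p = 7.1e-05), MHC class II genes of antigen presentation (-2.56, 7 of 7, 3.8e-04) and MHC class I (-1.50, 8 of 9, 5.1e-04) were lower. The interferon response (-1.56, 14 of 18, 2.0e-04), hypoxia and glycolysis (-1.24, 12 of 13, 5.9e-05) and mitochondrially encoded genes (-1.24, 13 of 13, 2.5e-05) were lower. So were the immediate early and dissociation genes (-0.69, 0.012), apoptosis genes (-1.09), cholesterol synthesis (-0.29), goblet markers (-1.25) and mast cell markers (-0.92), each of the last 4 with an adjusted p of 0.048. Among the lower genes were Cd74 (-2.56 ± 0.13), B2m (-2.41), Isg15 (-2.45 ± 0.28), Irf7 (-2.42), Oasl2 (-2.23), Car9 (-1.62) and Fabp1 (-3.42 ± 0.25). The p53 targets went both ways, with 9 higher and 13 lower adjusted over the list alone (median -0.27, camera adjusted p = 0.41, fry adjusted p = 0.012). Values went from Phlda3 (1.98 ± 0.21), Eda2r (1.61 ± 0.24) and Trp53inp1 (1.42 ± 0.22) to Cdkn1a (-1.64 ± 0.10). Lists not called by camera included the stem (0.84), proliferating (0.71), tuft (1.39), enteroendocrine (0.69), Paneth (0.00), M cell (0.34) and regenerative markers (-0.89), Notch (-0.11), YAP targets (-0.43) and inflammation (-0.62). In the matched comparison, with equal numbers of cells of like UMI totals, 11049 genes passed and the Wnt median was 2.26. Within the adenoma Wnt-high class 1664 of 12019 genes passed, with a Wnt median of 1.10 (adjusted p = 0.44 with an estimated correlation) and 2963 of 8361 calls turned in sign. Of the 2283 control cells of this class 2134 were Prox1-positive, so few Prox1-negative cells stand behind these values. With cells of that class matched for total UMIs, 1042 of 8973 genes passed, the Wnt median was 1.16 (adjusted p = 0.11 with an estimated correlation), and 2310 of 6243 calls turned in sign.

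**Figure D4:**
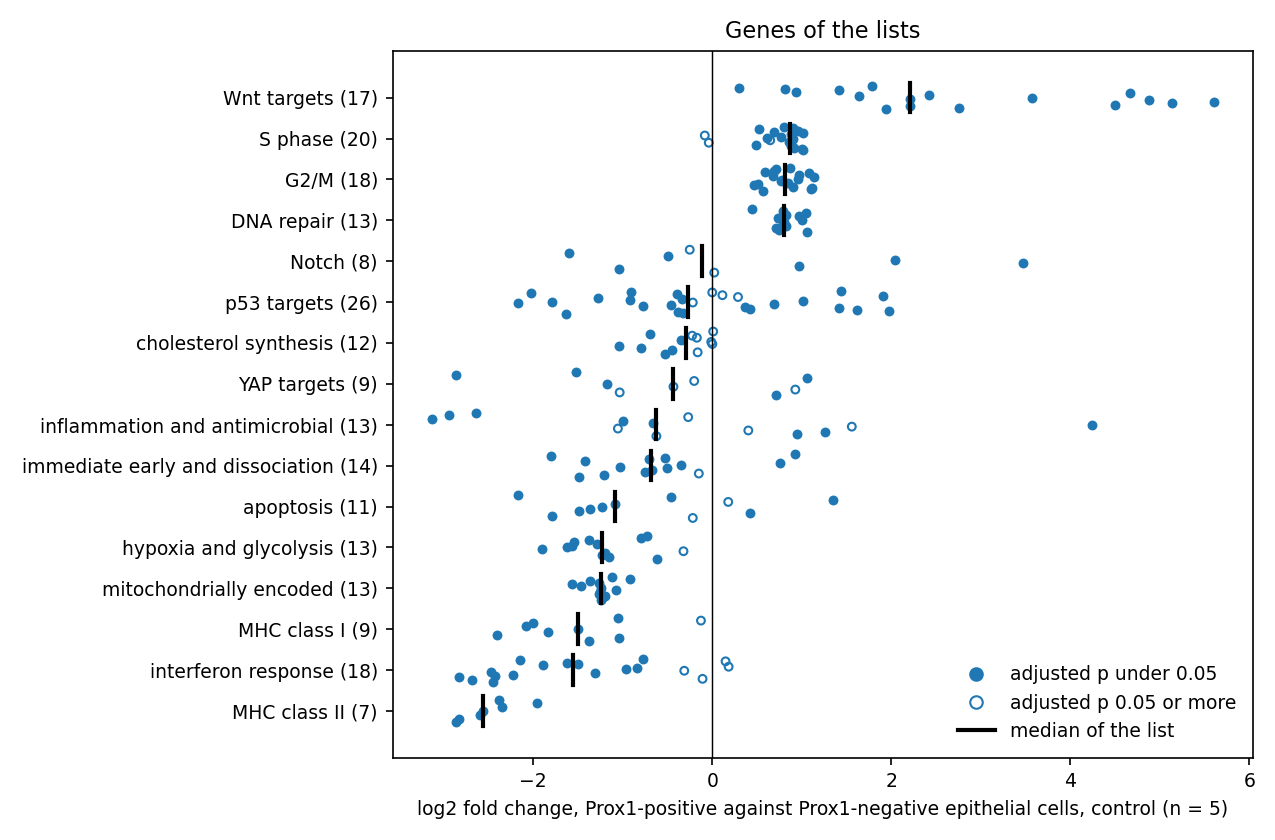
Log2 fold change of the members of the gene lists between Prox1-positive and Prox1-negative epithelial cells of the 5 control libraries; filled points have an adjusted p under 0.05 and the black bar is the list median. The lists shown are those of pathways and cell states, without the class markers. Wnt targets lie above 0, with a median of 2.21.

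Whether the RNA response at 1 d differed between Prox1-positive and Prox1-negative cells was tested as an interaction. The title names radioresistance, which this interaction does not test. Survival of cells was not followed, and Prox1 status was read from cells collected after irradiation. G2/M genes had lower values in Prox1-positive than in Prox1-negative cells relative to control, with a median of -0.60 and 0 of 18 positive. In this list 0 genes passed over all genes and 16 were lower adjusted over the list alone (camera adjusted p = 9.8e-18; adjusted p = 0.44 with an estimated correlation). Values went from Kif11 (-0.71 ± 0.17) and Cenpf (-0.69 ± 0.19) to Hmmr (-0.42) and Ccnb2 (-0.22). The sums cover all epithelial classes. In control, proliferating cells made up 23.4% of Prox1-positive and 5.00% of Prox1-negative cells, and their share of epithelial cells was lower at 1 d. No interaction was fitted within a class, so a change in makeup and a change within cells cannot be told apart. The p53 targets had a median of 0.28 with 20 of 26 positive, 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0051; adjusted p = 0.44 with an estimated correlation). Cdkn1a had the value 1.03 ± 0.14 (edgeR adjusted p = 0.14; 0.076 with the version as a covariate; 2.3e-06 by DESeq2). By edgeR 0 of 18909 genes passed, with 972 at an unadjusted p under 0.05 and 26 called by DESeq2, and 1 passed without control replicate 5. Other lists called with the preset correlation were S phase (-0.37, and adjusted p = 0.63 with an estimated correlation), DNA repair (-0.32, 0.63), proliferating markers (-0.65, 0.44), cholesterol synthesis (-0.30, 0.44), hypoxia and glycolysis (-0.12, 0.63) and neutrophil markers (-1.31, 0.44). So were MHC class II (0.57, 0.71), mitochondrially encoded genes (0.25, 0.81) and macrophage markers (0.80, 0.63). The Wnt targets (0.19) were not called.

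The shares of 21 cell classes were compared by exact two-sided permutation tests. At 1 d a single class at the smallest possible p (0.018) would have an adjusted p of 0.375, and at 2 d and 7 d (0.048) an adjusted p of 1.0, so a change in a single class could not pass there. The proliferating share of epithelial cells was 11.72% ± 4.45 (SD, n = 5; 6.95% to 16.51%) in control. It was 2.80% ± 1.11 (n = 3; 1.96% to 4.06%) at 1 d, 11.80% ± 4.16 (n = 2) at 2 d and 20.26% ± 0.39 (n = 2; 19.99% and 20.54%) at 7 d. The exact permutation p was 0.036, 0.95 and 0.095. Other classes with irradiated libraries fully apart from control were mast cells at 1 d (-0.92 percentage points), neutrophils (0.65) and fibroblasts (-2.01) at 2 d, and T cells (-4.22), B cells (-5.70), macrophages (-3.77) and Paneth cells (1.66) at 7 d. Over the alternatives the neutrophil difference at 2 d ranged from 0.30 to 1.01 and the macrophage difference at 7 d from -4.65 to -2.20. The B cell difference was -0.42 without control replicate 5. The Paneth difference ranged from 0.70 to 2.38 over the alternatives, with the highest value without IR 7 d replicate 1. Its denominator leaves out an unnamed cluster of 1540 cells led by the Paneth genes Defa22 and Defa21 (named after they were seen), with a median of 1118.5 UMIs and 89.5% of its cells from IR 7 d replicate 1. Also left out is an unnamed cluster of 3548 cells with Defa36, Defa30 and Defa17 among its leading genes. It had a median of 1042 UMIs, and IR 7 d replicate 2 gave most of its cells of any library (36.9%). A further unnamed cluster of 195 cells, led by Defa22, came mostly from control replicate 1 (59.5%). Whether RNA from the cells of these clusters adds to the Paneth values at 7 d was not tested. With all irradiated libraries against control, where a single class could pass, none did. The lowest adjusted p was 0.24, for dendritic cells, a difference of -1.12 percentage points (exact permutation p = 0.011). B cells made up 26.8% of the cells of control replicate 5 and 10.4% of IR 2 d replicate 2.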

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

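The weighing of the header versions by depth and of the p53 targets within version 6 libraries rests on tests chosen after the result was seen, and the fits with the header version as a covariate were added after the data had been seen.

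Control libraries with version 6 and version 7 headers differed in 7398 of 18368 genes. Across genes, the difference followed summed intron length (Spearman rho 0.551, over genes that are not independent replicates), and genes with a single exon were lower in version 7 than genes with introns by a median log2 difference of -0.529. A difference in summed UMIs is argued against, since the version 7 libraries span 41788858 to 109494181 UMIs in epithelial cells, on both sides of the version 6 libraries. A difference in UMIs per cell stays open, since the medians per epithelial cell were at most 18100.5 in the version 7 controls and at least 19843.5 in the version 6 ones. A candidate explanation is that reads over introns were counted in the version 7 libraries only, which could be settled from the counting settings; no biological explanation was tested, and mice or days that differ between the sets stay open.

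The rise of p53 targets at 1 d was weighed against 3 technical explanations. The median was 1.10 within version 6 libraries, 0.91 without IR 1 d replicate 1, the library with most barcodes and fewest epithelial cells, and 1.30 within the adenoma Wnt-high class. Thus neither the header version, nor that library, nor a change in the makeup of the epithelium accounts for it as a whole. Over the 56 splits of the 8 libraries into groups of the same sizes, only the real one reached the median of 1.00. The highest other split gave 0.73, which argues against chance, at the smallest share that 56 splits allow (0.018). These values are consistent with a p53 response to irradiation, as a hypothesis found and tested on the same data.

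Wnt targets were higher in Prox1-positive cells (median 2.21). More UMIs per Prox1-positive cell is argued against, since the median was 2.26 with matched cells. Within the adenoma Wnt-high class it was 1.10 (1.16 with matched cells), so a part of the difference may come from the classes that make up the cell groups, and how large a part cannot be told apart here because that class was itself named from Wnt genes. That class also held few Prox1-negative cells, since 2134 of its 2283 control cells were Prox1-positive.

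For the 1 d comparison, 2 of 56 splits gave as many genes as the real one (16); the other, with 9608 genes, set control replicates 4 and 5 with IR 1 d replicate 3 and so follows the header version, a structure of the samples. Within version 6, 4 genes were called, and within version 7, 3, where IR 1 d replicate 3 is the only irradiated library and is assumed to vary like the other groups. With the version as a covariate, 2 of 55 splits reached the real count of 51, and the highest other, control replicate 3 with IR 1 d replicates 2 and 3, gave 620, which points to a structure of the samples other than the version. These 3 libraries have the highest enterocyte shares of the epithelial cells (35.12%, 35.77% and 36.09%), and whether that underlies the count was not tested. For all irradiated libraries, 4 of 100 splits gave at least the real count of 1, with 7844 in the split of control replicates 4 and 5, IR 1 d replicate 3, IR 2 d replicate 1 and IR 7 d replicate 1, which also follows the header version. With the version as a covariate 6 genes were called. The shares were under 0.05 in these 3 results, without adjustment over them, and do not exclude chance. The counts themselves are small beside those of the highest other splits. For all irradiated libraries the count is 1 gene, and no splits with the version as a covariate were made for it. For the interaction, 56 of 56 splits gave at least the real count of 0, as any split must, so this count says nothing about chance. The highest other split gave 699, which points to a structure of the samples that was not tested. For Prox1-positive against Prox1-negative cells the 16 possible swaps are too few for a share under 0.05; 1 of 16 reached the real counts of 11245 and 11273, and the highest other gave 0.

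Of 78 groups of 5 control values, 6 held a library far from the others, where chance gives about 1 in 20. Control replicate 5 had a median of 24.7% mitochondrial UMIs over barcodes, 26.8% B cells among all cells and 3.10% tuft cells among epithelial cells, and Neurog3 stood at 3.19 CPM in it. Control replicate 4 held 4246 epithelial cells. Isg15 stood at 61.15 CPM in control replicate 1.

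Differences between the times were tested as 7 d against 1 d. Genes past the threshold were Gsdmc4 (4.67), Gsdmc3 (4.28), Gsdmc2 (3.91), Ephx1 (-3.17) and Inka2 (-4.22). Lists called with the preset correlation had medians of -1.03 for p53 targets, 0.79 for S phase, 1.31 for G2/M and 0.98 for DNA repair. They were -1.08 for the interferon response, -0.90 for MHC class I, -0.48 for hypoxia and glycolysis, 0.99 for inflammation and antimicrobial genes and -0.37 for mitochondrially encoded genes. Class markers had medians of 1.20 for proliferating markers, -1.58 for enterocyte markers, -2.04 for goblet markers and -1.58 for T cell markers. With an estimated correlation the p53 targets alone were called (adjusted p = 0.041).

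Differences between Prox1-positive and Prox1-negative cells in the 1 d response were tested as an interaction. The sums cover all epithelial classes, so a change in makeup is not excluded. The list medians were 0.28 for p53 targets, -0.37 for S phase, -0.60 for G2/M, -0.32 for DNA repair and 0.57 for MHC class II. They were -0.12 for hypoxia and glycolysis, -0.30 for cholesterol synthesis, 0.25 for mitochondrially encoded genes, -0.65 for proliferating markers, 0.80 for macrophage markers and -1.31 for neutrophil markers. None of these lists was called with an estimated correlation (adjusted p from 0.44 to 0.81). The tdTomato line, which entered no comparison, stood at 19.4 CPM in IR 2 d replicate 1 and 3.84 CPM in IR 2 d replicate 2, on both sides of the 10.0 CPM of control replicate 5.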

How the results depend on the processing

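The fits with the header version, those within a version and those without the highest doublet scores were tests chosen after the data had been seen. Over all alternatives, 189 values of the comparisons were labelled the same, 69 moved and 10 reversed. A count was labelled the same when it stayed within 1.5 times the main one. A difference in the Prox1 share was labelled the same when its sign and its side of the test threshold held, whatever its size. Of the gene list values, taken from the fits in which lists were tested, 251 were the same, 138 weaker and 7 reversed. The fits within a version gave list medians without a list test and are not in these counts: of 68 medians of lists called in the pooled IR comparisons, 4 turned in sign. These were MHC class II at 1 d (0.47) and, for all irradiated libraries, S phase (0.12), proliferating markers (0.071) and hypoxia and glycolysis (0.084), each within version 7. Of the named gene values 5760 were the same, 298 weaker, and 94 stronger. Another 108, called neither in the main fit nor in the alternative, turned in sign by at least their SE, and no value called in either turned in sign. The cause was not tested where none is named.

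DESeq2 called 149 genes at 1 d, 37 at 2 d, 16 at 7 d, 28 for all irradiated libraries, 414 for 7 d against 1 d and 26 for the interaction. With control replicates 3 to 5 only, edgeR called 0 in the 1 d, 2 d, all-IR and 7 d against 1 d comparisons, with fewer samples (664, 234, 145 and 1821 at an unadjusted p under 0.05). The labels of control replicates 1 and 2 have another protocol text and no library name, so these libraries may be another batch. Whether the calls ended from fewer samples or from such a batch was not tested. The p53 medians in these fits were 1.08 at 1 d, 0.72 at 2 d and 0.58 for all irradiated libraries. Stricter cells gave 3 genes at 2 d and 2 for all irradiated libraries. With only the groups compared in the fit, 2 genes were called at 1 d, 0 at 2 d and 0 for 7 d against 1 d. The header version as a covariate gave 51, 3, 6 and 10 genes at 1 d, 2 d, for all irradiated libraries and for 7 d against 1 d. Version 7 libraries alone gave 3 (from a single irradiated library), 0 and 0 at 1 d, 2 d and for all, 0 for 7 d against 1 d (2974 at an unadjusted p under 0.05), and version 6 libraries alone 4 at 1 d. With each library left out in turn the counts ranged from 2 to 21 at 1 d, 0 to 2 at 2 d and 0 to 0 at 7 d. At an unadjusted p under 0.05 they ranged from 689 to 1206 at 1 d, 242 to 1575 at 2 d, 217 to 1239 at 7 d and 1061 to 4095 for 7 d against 1 d. The called counts ranged from 0 to 3 for all irradiated libraries, 0 to 5 for 7 d against 1 d and 0 to 1 for the interaction. The ranges were 10002 to 11055 and 10048 to 11105 for Prox1-positive against Prox1-negative cells with and without the enteroendocrine and tuft clusters. Prox1-positive against Prox1-negative counts stayed within 1.5 times in 14 of 14 alternatives each.

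Samples of the same replicate number share only a number: same-numbered deviations correlated at 0.13, -0.17 and 0.11 between IR 1 d and control, -0.02 at 2 d, -0.11 at 7 d, and 0.43 between 7 d and 1 d. With the replicate number as a block, the counts were 0 at 1 d (1043 at an unadjusted p under 0.05), 7322 at 2 d, 2077 at 7 d and 6249 for 7 d against 1 d. At 2 d and 7 d these fits keep control replicates 1 and 2, and for 7 d against 1 d they keep IR 1 d replicates 1 and 2. These all have version 6 headers while the libraries set against them have version 7 headers, so group and version cannot be told apart in these 3 fits.

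Differences in the Prox1 share reversed at 1 d with control replicates 3 to 5 only (1.98 percentage points) and without control replicate 2 (0.50) or 4 (0.53) or IR 1 d replicate 2 (4.596) or 3 (1.86). At 7 d they reversed after thinning (-0.33), with 2 Prox1 UMIs (-0.069) and without control replicate 3 (-1.16) or IR 7 d replicate 1 (-8.65). For all irradiated libraries the difference reversed with control replicates 3 to 5 only (1.34). Their ranges over left-out libraries were -13.0 to 4.596 at 1 d, -15.0 to -7.51 at 2 d, -8.65 to 15.9 at 7 d and -7.61 to -0.11 for all. The class shares gave 0 calls in all 18 alternatives, which at 1 d, 2 d and 7 d shows nothing, since a single class could not pass adjustment there. The difference in the proliferating share ranged from -11.33 to -7.61 percentage points at 1 d and from 7.35 to 9.86 at 7 d.

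Of the list calls with the preset correlation, 53 in the IR comparisons became 3 with an estimated correlation (4 with the version as a covariate too), and 16, 13 and 11 in the Prox1, Prox1 without enteroendocrine and tuft, and interaction comparisons became 0, 0 and 0. For all irradiated libraries the pooled medians were negative and reversed with the version as a covariate for S phase (0.059), G2/M (0.0013) and proliferating markers (0.069), and with the covariate and without IR 1 d replicate 1 for S phase (0.15), G2/M (0.13), proliferating markers (0.19) and the interferon response (0.012). Depth limits the share of cells with a Prox1 UMI, which in control was 39.3% as measured and 24.99% after thinning. No setting varied depth for the counts of genes. At the same depth, 7% of simulated 2-fold changes at 1 d were recovered, and 57% with the version as a covariate. There the biological coefficient of variation fell from 0.504 to 0.294. Since counts were simulated with the dispersion of each fit, the higher recovery follows from the lower dispersion. What limits the counts of genes in the real libraries was not tested.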

Other observations

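The tests within single cell classes were chosen after the data had been seen.

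Within single classes, the p53 targets were higher at 1 d in every class tested for them at that time, from a median of 0.37 in enterocytes to 1.30 in adenoma Wnt-high cells, and each call held with an estimated correlation (adjusted p from 7.4e-04 to 0.0092). In the adenoma Wnt-high class (4984 cells in 12 libraries, held by different clusters in the header versions), 46 genes were higher and 1 was lower of 16069 at 1 d by edgeR. They were led by Inka2 (4.73 ± 0.20, adjusted p = 2.5e-06), Ephx1 (2.87 ± 0.21), Zmat3 (1.92 ± 0.17) and Psrc1 (3.31 ± 0.30). In this class 7 genes were higher at 2 d and 0 at 7 d, with 635 at an unadjusted p under 0.05 there; DESeq2 was not run on single classes. These genes were named after their values were seen. The p53 list median in this class was 1.30 at 1 d, 1.03 at 2 d and 0.25 at 7 d, with 12 members called over all genes and 21 adjusted over the list alone at 1 d. With the version as a covariate the 7 d median was 0.47 with 11 adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). In proliferating cells the median was 1.13 at 1 d, with 20 members adjusted over the list alone, and in goblet cells 0.97 with 17. It was 0.99 with 10 in plasma cells, 0.99 with 12 in fibroblasts, 0.88 with 13 in blood endothelium, 0.58 with 8 in macrophages and 0.51 with 9 in T cells. In the clusters of these 5 classes, epithelial markers were detected on average in 29.5% to 45.5% of cells, and doublets are largely still present. Whether epithelial RNA in these sums adds to the medians was not tested. Eda2r rose in goblet cells (5.00 ± 0.41, adjusted p = 0.0013) and in blood endothelium (3.74 ± 0.48, adjusted p = 0.0081), and Mbl2 in enterocytes (4.54 ± 0.40, adjusted p = 0.0035).

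G2/M genes were lower in blood endothelium, with medians of -2.39 at 1 d (16 of 16 lower adjusted over the list alone; adjusted p = 0.052 with an estimated correlation, and 0.028 with the version as a covariate too). They were -3.42 at 2 d (15; adjusted p = 0.14) and -0.32 at 7 d. In fibroblasts they were -1.18 at 1 d and -2.38 at 2 d, and in macrophages -1.03 and -1.53, with adjusted p = 0.13, 0.084, 0.075 and 0.25 with an estimated correlation. In proliferating epithelial cells, a class named from such genes, the median at 1 d was 0.10. Some libraries held few cells of these classes. Blood endothelium had 13 cells in control replicate 5 and 239 in control replicate 1. It had 178, 167 and 20 in IR 1 d replicates 1 to 3, and 50 and 55 at 2 d. Fibroblasts had 44 and 30 cells at 2 d, and the proliferating class 12, 52 and 79 at 1 d. The p53 medians of these classes rest on the same sums. Whether the classes differ from each other was not tested.

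The tdTomato line was present in control replicate 5 (775 UMIs, 10.0 CPM), IR 2 d replicate 1 (2553, 19.4 CPM) and IR 2 d replicate 2 (410, 3.84 CPM). In IR 2 d replicate 1 it had a UMI in 43.7% (95% Wilson interval 40.8 to 46.6) of Prox1-positive epithelial cells, at a median of 20870 UMIs, and in 11.1% (9.93 to 12.4) of Prox1-negative ones (15636.5 UMIs). It had a UMI in 54.8% of adenoma Wnt-high cells and in 2.33% of T cells (5775 UMIs). In IR 2 d replicate 2 the shares were 19.8% of Prox1-positive and 7.61% of Prox1-negative cells, 25.1% of adenoma Wnt-high and 0.36% of T cells. In control replicate 5 they were 31.9% of Prox1-positive and 9.06% of Prox1-negative cells, 46.6% of adenoma Wnt-high cells and 7.33% of enterocytes, against 1.52% of T cells.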
